A study of Mus musculus with 17 samples.

How the data were processed

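RNA of mouse CD8+ T cells was sequenced after removal of ribosomal RNA with a stranded total RNA kit, as paired-end reads, per the labels' protocols. The authors deposited 1 table of whole-number read counts per library, with 53679 genes by Ensembl identifier, of which 24955 had 0 counts in every library. A table joining the same libraries was not used here. Per the submitters' processing notes, the tools were STAR 2.5.2 and RSEM 1.3.0 and the genome build GRCm38 (mm10). RSEM estimates counts that need not be whole, and whether the deposited counts were rounded, which annotation release was used and how strand was set are not given in the sources used here. Symbols, positions, gene types and GC content were taken from a GENCODE annotation of GRCm38, which matched 53565 identifiers. Genes with near-identical copies or overlapping neighbours share reads that counting may divide between them, so their values are uncertain.

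Groups and replicate numbers came from the labels. Counts were fitted as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr by group (16246 tested), libraries scaled by the trimmed mean of M values, and robust quasi-likelihood models fitted to all 17 libraries with 1 coefficient per group, so that all groups shared 1 estimate of the spread (common biological coefficient of variation 0.153). The 13 contrasts were KO against WT in 3 states, each stimulation against unstimulated cells per genotype, anti-CD28 added per genotype, KO cells given anti-CD3 against WT cells given both antibodies, and 3 interactions. P-values were adjusted by Benjamini-Hochberg within a contrast, with a threshold of 0.05. CPM used TMM-scaled totals, and SEs come from the fitted log2 fold changes. Depth limits precision for low genes such as Il2 and Csf2, which lay near 0 counts in unstimulated cells.

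Gene lists numbering 31 were fixed before the data were examined, on receptor signalling, cytokines, interferon responses, receptors, differentiation, cell cycle, metabolism, stress, other cell types and RNA quality (603 of 604 genes found). They were tested with camera in limma 3.58.1 (inter-gene correlation 0.01, log2 CPM with a prior count of 2), adjusted within a contrast, and again with a correlation estimated from the data, which 10 of the 136 calls over 403 tests passed. Members past the threshold were counted over all genes tested and adjusted over the list alone. Not every list is described in every comparison, and some results on named genes are not reported here. Named genes followed a rule fixed in advance: 25 fixed genes of T cell activation, the 8 highest and lowest values per contrast among called genes of mean log2 CPM of at least 2 whose groups did not overlap (chance 10% for 3 against 3), without predicted genes and, for interactions, without the overlap criterion, and up to 4 members per direction of each list by smallest adjusted p.

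Alternatives chosen before the data were examined were relative log expression scaling, DESeq2 1.42.0, limma voom with quality weights, no filter, a filter of 1 CPM in 3 libraries, only the groups compared, the replicate number as a block, leaving out each library, and for lists an estimated correlation and fry. A correction for GC content and a fit without KO both-antibody replicate 3 and KO unstimulated replicate 2 were added after the data were seen. For the correction a loess curve (span 0.3) of log2 CPM on GC content, over genes of mean log2 CPM of at least 1, gave each library's offsets (99.9% of tested genes had a GC value). On simulated counts with known 2-fold changes, edgeR called 98.5% of changed genes for KO against WT with anti-CD3 (15887 genes fitted). With a GC trend added to 1 group, 2119 unchanged genes were called without and 10 with the correction. Camera called 0 of 30 unmoved lists. The simulated genes varied independently, so this does not test how often lists of correlated genes are called without a change. Figures were drawn with matplotlib 3.10.9.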

Results

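The data were gene-level RNA sequencing read counts of 17 libraries of CD8+ T cells from C57BL/6 mice, wild type (WT) or knockout (KO) for Cblb. Cblb encodes Cbl-b, an E3 ubiquitin ligase known to restrain T cell activation and to set the need for costimulation through CD28. Cells were unstimulated or stimulated in 12 h experiments with anti-CD3, which engages the T cell receptor complex, or with anti-CD3 plus anti-CD28, which adds the costimulatory signal. The study's stated subject is the excess interferon-gamma made by CD8+ T cells without Cbl-b and their resistance to regulatory T cells. The 6 groups held 3 libraries each, except WT cells given both antibodies, with 2 (replicates 2 and 3). Replicate 1 of that group was not analysed here. Total counts per library were 16635826 to 38269033, and 160059285 in KO unstimulated replicate 2. No label says that the replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. Each pair of replicates differed by more than sampling noise (chi-square per gene 4.03 to 629), so no library was counted as a duplicate of another.

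The libraries also differed in a trend with the GC content of genes. The tilt of a library was the median log2 deviation of expressed protein-coding genes of at least 56% GC minus that of genes of at most 40% GC. It was 1.14 in KO unstimulated replicate 2 and -1.15 in KO both-antibody replicate 3, and -0.74 to 0.56 in the other libraries. The small RNAs of the signal recognition particle and of 7SK (Rn7s1, Rn7s2 and Rn7sk, the first 2 near-identical copies whose reads cannot be told apart with certainty) took 2.65% to 13.1% of the counts, and mitochondrially encoded genes 2.25% to 5.54%. Levels are given below as CPM (read counts scaled to a common library total), mean ± SD over the libraries of a group (n = 3, or n = 2 for WT cells given both antibodies). Differences are log2 fold changes ± SE, with adjusted p from edgeR's quasi-likelihood test and the Benjamini-Hochberg method, and gene lists were tested with camera. Members of a list called over all genes are counted first, and then those called when p is adjusted over the list alone (within the list). Where a correction for the GC trend changed a call, this is stated.

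Cblb (ENSMUSG00000022637; GRCm38 chromosome 16, 52031225 to 52208048, plus strand, protein coding) was lower in every KO library than in every WT library. Unstimulated libraries held 139.5 to 159.7 CPM in WT and 63.9 to 68.8 CPM in KO. With anti-CD3 the ranges were 180.4 to 190.1 and 78.4 to 83.8 CPM, and with both antibodies 178 to 179 and 80.2 to 95.9 CPM. The log2 fold change of KO against WT was -1.16 ± 0.083 unstimulated, -1.21 ± 0.083 with anti-CD3 and -1.05 ± 0.090 with both antibodies (adjusted p = 1.15e-06, 5.66e-07 and 2.29e-05). In a fit of the 5 both-antibody libraries alone the last of these had adjusted p = 0.197 (range over its alternatives 7.31e-27 to 0.197). The counts cover the whole gene and the labels do not say which part of it was removed, so the remaining KO counts do not show how much intact transcript was left.

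**Figure D1:**
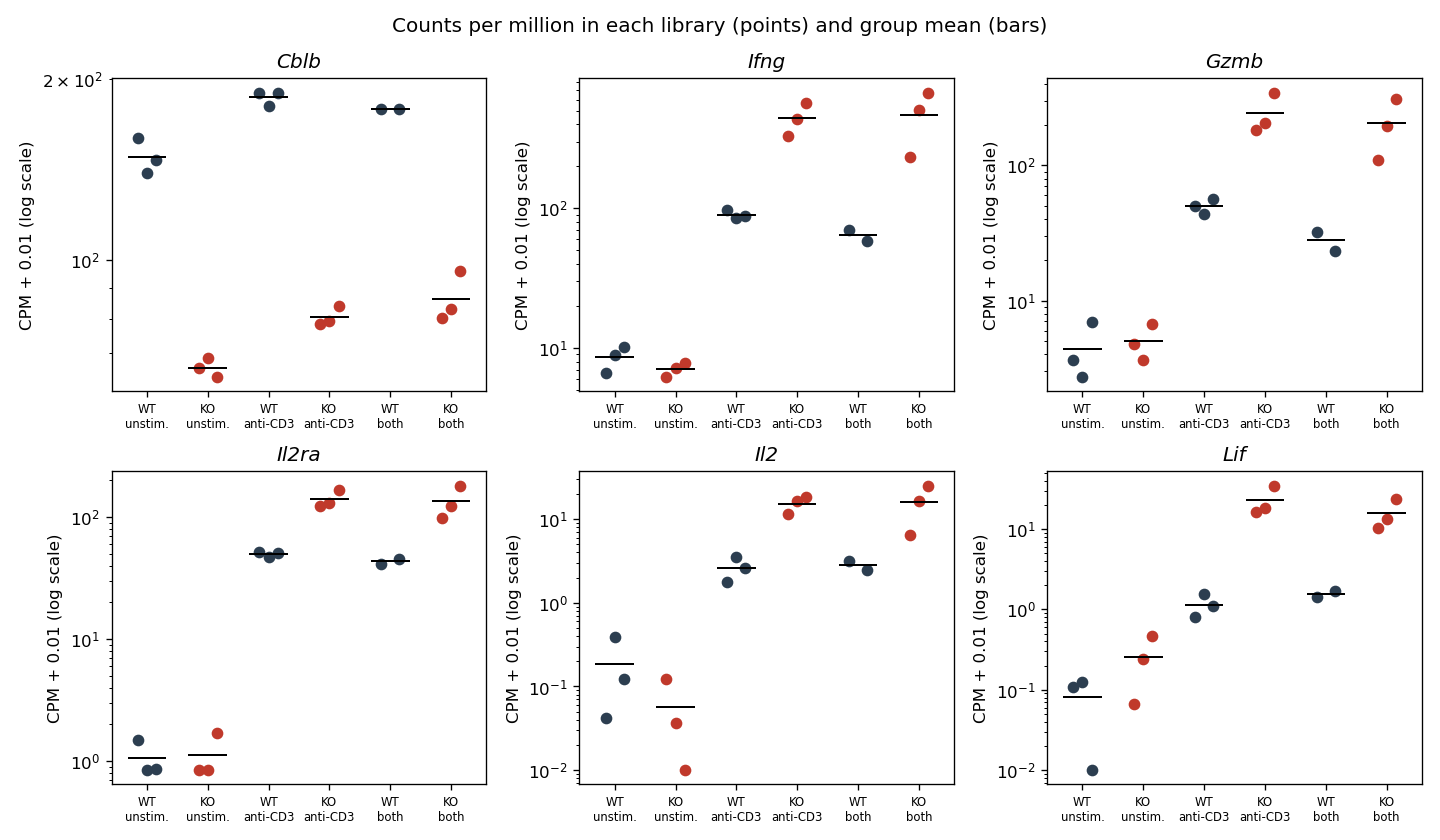
Levels of Cblb, Ifng, Gzmb, Il2ra, Il2 and Lif in each library, in CPM on a log scale (0.01 was added so that 0 could be drawn), by group; points are libraries and bars group means. Cblb averaged 187 CPM in WT and 80.5 CPM in KO cells given anti-CD3, while Ifng averaged 90.2 and 446 CPM.

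KO and WT cells given anti-CD3 alone were compared first. Several effector cytokine transcripts were higher in KO cells. Ifng, which encodes interferon-gamma, averaged 446 ± 122 CPM in KO and 90.2 ± 6.32 CPM in WT cells, a log2 fold change of 2.31 ± 0.30 (adjusted p = 0.000313), with all 3 KO libraries above all 3 WT libraries. Tnf, Il2, Csf2 (GM-CSF) and Lta (lymphotoxin alpha) were higher by 1.198 ± 0.17, 2.51 ± 0.44, 1.88 ± 0.38 and 1.99 ± 0.23 (adjusted p 8.39e-05 to 0.0033). Lif, leukaemia inhibitory factor, averaged 23.1 ± 10.1 CPM in KO and 1.14 ± 0.367 CPM in WT cells (4.29 ± 0.40, adjusted p = 1.86e-05). Among T cell cytokines the count was 11 of 15 higher and 0 lower (11 and 0 within the list, median 1.198, adjusted p = 1.95e-08, or 0.0493 with estimated correlation).

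Some cell killing and chemokine genes were higher in KO cells given anti-CD3. Granzyme B (Gzmb) averaged 245 ± 88.2 CPM in KO and 50.2 ± 6.31 CPM in WT cells (2.29 ± 0.39, adjusted p = 0.00218), and perforin (Prf1) and the granule protein gene Nkg7 were higher by 0.66 ± 0.12 and 1.03 ± 0.14 (adjusted p = 0.00124 and 0.000167). The list of cytotoxic granule and death ligand genes had 6 of 14 higher and 0 lower (6 and 0 within the list, median 0.46, adjusted p = 0.0176, or 0.285 with estimated correlation). Without WT anti-CD3 replicate 1 its adjusted p was 0.0574. The chemokine genes Ccl3, Ccl4, Ccl1 and Xcl1 were higher by 1.82 ± 0.22, 1.45 ± 0.14, 1.45 ± 0.20 and 0.91 ± 0.15 (adjusted p 1.37e-05 to 0.000792). Chemokines as a list had 6 of 8 higher and 0 lower (6 and 0 within the list, median 1.10, adjusted p = 0.000242, or 0.118 with estimated correlation).

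Genes induced early by the T cell receptor had 16 of 23 higher and 0 lower (19 and 0 within the list, median 0.55, adjusted p = 4.73e-10, or 0.0593 with estimated correlation). Il2ra, the high-affinity subunit of the interleukin-2 receptor, averaged 139.9 ± 23.4 CPM in KO and 49.7 ± 2.56 CPM in WT cells. The log2 fold changes of Il2ra, Myc, Nr4a3 and Irf4 were 1.496 ± 0.20, 1.37 ± 0.12, 1.04 ± 0.15 and 0.55 ± 0.13 (adjusted p 8.88e-06 to 0.00988). The early activation marker Cd69 had 0.39 ± 0.20 (adjusted p = 0.208), which passed without KO both-antibody replicate 1 (adjusted p = 0.0372), with the GC correction and in a fit of the 6 anti-CD3 libraries alone (range over alternatives 0.0132 to 0.549). Targets of interleukin-2 and STAT5 signalling had 15 of 20 higher and 1 lower (15 and 1 within the list, median 0.86, adjusted p = 2.15e-09, or 0.0493 with estimated correlation). They included Cish, an inhibitor induced by STAT5, and the cell cycle kinase gene Cdk6, higher by 2.60 ± 0.24 and 1.79 ± 0.16 (adjusted p = 1.37e-05 and 8.17e-06). Bcl6, which STAT5 is known to repress, was lower (-0.78 ± 0.15, adjusted p = 0.00243).

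Some genes of growth and division were higher in KO cells given anti-CD3. Ribosome biogenesis had 22 of 25 higher and 0 lower (25 and 0 within the list, median 0.67, adjusted p = 9.78e-17, or 0.0593 with estimated correlation). Rrp12, Fbl and Nolc1 were higher by 1.15 ± 0.14, 0.96 ± 0.10 and 0.93 ± 0.10 (adjusted p 3.69e-05 to 9.68e-05). Amino acid transport and ATF4 targets had 18 of 21 higher and 0 lower (19 and 0 within the list, median 0.99, adjusted p = 7.92e-12, or 0.0493 with estimated correlation). Mthfd2, a folate enzyme, and the amino acid transporter gene Slc7a5 were higher by 1.12 ± 0.13 and 1.08 ± 0.13 (adjusted p = 7.81e-05 and 7.04e-05). Glycolysis genes had 14 of 20 higher and 0 lower (15 and 0 within the list, median 0.58, adjusted p = 6.51e-07, or 0.0704 with estimated correlation), with hexokinase 2 (Hk2) and Tpi1 higher by 1.16 ± 0.15 and 1.09 ± 0.13 (adjusted p = 0.000126 and 9.68e-05). DNA replication genes had 16 of 25 higher and 0 lower (20 and 0 within the list, median 0.56, adjusted p = 7.92e-12, or 0.0704 with estimated correlation). The helicase gene Mcm5 and Uhrf1 were higher by 1.00 ± 0.11 and 1.81 ± 0.19 (adjusted p = 4.21e-05 and 2.85e-05). Mitosis genes had 10 of 22 higher and 0 lower (17 and 1 within the list, median 0.89, adjusted p = 1.51e-05, or 0.281 with estimated correlation). Cdk1 and Top2a were higher by 1.43 ± 0.32 and 1.24 ± 0.26 (adjusted p = 0.0069 and 0.00526). Nuclear-encoded oxidative phosphorylation genes had 10 of 25 higher and 0 lower (15 and 0 within the list, median 0.37, adjusted p = 3.13e-06, or 0.173 with estimated correlation). Cholesterol synthesis genes had 8 of 24 higher and 0 lower (11 and 0 within the list, median 0.31, adjusted p = 0.00104, or 0.173 with estimated correlation).

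In KO cells given anti-CD3, NF-kappaB targets and survival genes had 10 of 23 higher and 1 lower (13 and 2 within the list, median 0.36, adjusted p = 2.36e-05, or 0.0704 with estimated correlation). The anti-apoptotic genes Bcl2l1 and Bcl2 were higher by 1.71 ± 0.14 and 0.94 ± 0.13 (adjusted p = 3.08e-06 and 0.000185). Heat shock genes had 8 of 16 higher and 0 lower (8 and 0 within the list, median 0.55, adjusted p = 0.000673, or 0.308 with estimated correlation), including Hsp90ab1 (0.66 ± 0.088, adjusted p = 0.000187). The T-box transcription factor genes Eomes and Tbx21, Bhlhe40 and Cd44 were higher by 1.52 ± 0.16, 1.33 ± 0.16, 1.33 ± 0.26 and 0.64 ± 0.15 (adjusted p 2.85e-05 to 0.00731). Memory and effector CD8 genes as a list had 11 of 29 higher and 2 lower (14 and 3 within the list, median 0.22, adjusted p = 0.0367, or 0.335 with estimated correlation). Without KO anti-CD3 replicate 3 and without WT anti-CD3 replicate 1 its adjusted p was 0.0517 and 0.11. Naive and quiescence genes had 0 of 24 higher and 9 lower (1 and 13 within the list, median -0.27, adjusted p = 1.04e-08, or 0.0593 with estimated correlation). The interleukin-7 receptor gene Il7r and the egress receptor gene S1pr1 were lower, at -0.57 ± 0.10 and -0.57 ± 0.080 (adjusted p = 0.00148 and 0.000261). Tcf7, which encodes TCF-1, had -0.22 ± 0.11 (adjusted p = 0.174; 0.00352 to 0.453 over its alternatives, and 0.00352 with the GC correction).

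Inhibitory receptor and exhaustion genes were mixed in KO cells given anti-CD3. Cd200, Entpd1 (the ectonucleotidase CD39), Lag3 and Pdcd1 (PD-1) were higher by 1.54 ± 0.25, 1.06 ± 0.24, 0.97 ± 0.22 and 0.61 ± 0.15 (adjusted p 0.000831 to 0.0099). Havcr2, Tigit and Ctla4 had 0.70 ± 0.41, 0.21 ± 0.33 and -0.014 ± 0.16 (adjusted p 0.271 to 0.968). Havcr2 passed in a fit of the 6 anti-CD3 libraries alone (adjusted p = 0.0451). Inhibitory receptors and exhaustion genes as a list had 4 of 17 higher and 1 lower (6 and 1 within the list, median 0.21, adjusted p = 0.118), and passed, as higher, without WT anti-CD3 replicate 2 (adjusted p = 0.0364). The receptor of transforming growth factor beta, the product of Tgfbr2, and its inhibitor Smad7 had -0.29 ± 0.098 and -0.21 ± 0.10 (adjusted p = 0.0566 and 0.184). Over their alternatives adjusted p was 0.00325 to 0.26 and 0.000312 to 0.432. Both passed, as lower, with the GC correction (adjusted p = 0.00589 and 0.000312), limma voom (0.00521 and 0.0177), the groups compared alone (0.00325 and 0.0118) and without the 2 libraries of most extreme GC tilt (0.00487 and 0.034). Tgfbr2 also passed with relative log expression scaling, the CPM filter, DESeq2 and the replicate block (adjusted p 0.0073 to 0.0471), and without any 1 of 6 libraries (adjusted p 0.0177 to 0.0484). TGF-beta pathway genes had 3 of 18 higher and 1 lower (3 and 4 within the list, median -0.073, adjusted p = 0.357), with a mean of 0.019 that differs in sign from the median. Cd28 itself was lower, at -0.36 ± 0.12 (adjusted p = 0.0433). Costimulatory receptors had 3 of 15 higher and 3 lower (5 and 3 within the list, median -0.037, adjusted p = 0.948), with a mean of 0.18.

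The interferon response lists did not pass in this comparison. In KO cells given anti-CD3, IFN-gamma response genes had 2 of 36 higher and 9 lower (3 and 12 within the list, median -0.030, adjusted p = 0.0746). With the GC correction the median was -0.15 and adjusted p = 0.00277, and the list also passed, as lower, without WT anti-CD3 replicate 3, KO unstimulated replicate 2 or KO unstimulated replicate 3 (adjusted p = 0.0174, 0.0494 and 0.0036). The guanylate-binding protein genes Gbp7 and Gbp8 and the interferon signalling gene Irf9 were lower, at -0.61 ± 0.13, -0.62 ± 0.12 and -0.44 ± 0.11 (adjusted p 0.00189 to 0.0156). The transcription factor gene Irf8 was higher by 1.73 ± 0.15 (adjusted p = 8.17e-06). Type I interferon response genes had 1 of 26 higher and 3 lower (1 and 3 within the list, median -0.16, adjusted p = 0.114), and passed, as lower, without WT anti-CD3 replicate 3 or KO unstimulated replicate 3 (adjusted p = 0.0285 and 0.0454). The other lists that did not pass were negative regulators of antigen receptor signalling (5 of 30 higher and 3 lower, 5 and 3 within the list, adjusted p = 0.511), apoptosis and p53 targets (6 of 20 higher and 2 lower, 8 and 2 within the list, adjusted p = 0.19), mitochondrially encoded genes (0 of 13 called, also within the list, adjusted p = 0.118, and 0.0373 without the 2 libraries of most extreme GC tilt) and the sex-linked genes kept as a library check (0 of 2 called, also within the list, adjusted p = 0.929).

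Among the lowest values in KO cells given anti-CD3, besides Cblb, were those of Gria3, a glutamate receptor subunit, Pcsk1, Cd96, Dntt and the sialyltransferase gene St8sia6, at -1.52 ± 0.30, -1.26 ± 0.26, -1.22 ± 0.12, -1.10 ± 0.23 and -1.06 ± 0.24 (adjusted p 1.47e-05 to 0.00722). Over all genes, 1713 were higher and 779 lower of 16246 tested (68.7% of calls higher), 387 and 42 of them by 2-fold or more. Relative log expression scaling gave 1428 higher and 1070 lower, DESeq2 1720 and 1387, and the GC correction 1945 and 1586 (55.1% higher), with 2081 genes called in the same direction in both fits. Of the 25 genes fixed in advance, 14 were higher and 4 lower. The count of calls was 853 without KO anti-CD3 replicate 3, 1268 without WT anti-CD3 replicate 3 and 1348 without WT anti-CD3 replicate 2. Of the 55 named genes called, 8 lost their call without KO anti-CD3 replicate 3 (adjusted p 0.0506 to 0.122: Irf4, Cd44, Cdk1, Pdcd1, Lag3, Cd28, Irf9 and St8sia6), 3 without WT anti-CD3 replicate 3 (adjusted p 0.059 to 0.0984: Irf4, Pdcd1 and Cd28), 2 without WT anti-CD3 replicate 2 (adjusted p 0.0574 to 0.151: Cd28 and Irf9) and 2 without WT anti-CD3 replicate 1 (adjusted p 0.057 to 0.0685: Cd28 and Irf9). Cd28 also lost its call without KO anti-CD3 replicate 1 or 2, KO both-antibody replicate 2, WT both-antibody replicate 3 or WT unstimulated replicate 2 or 3 (adjusted p 0.0549 to 0.132). Pdcd1 and Lag3 lost theirs with the GC correction (adjusted p 0.099 to 0.137).

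**Figure D2:**
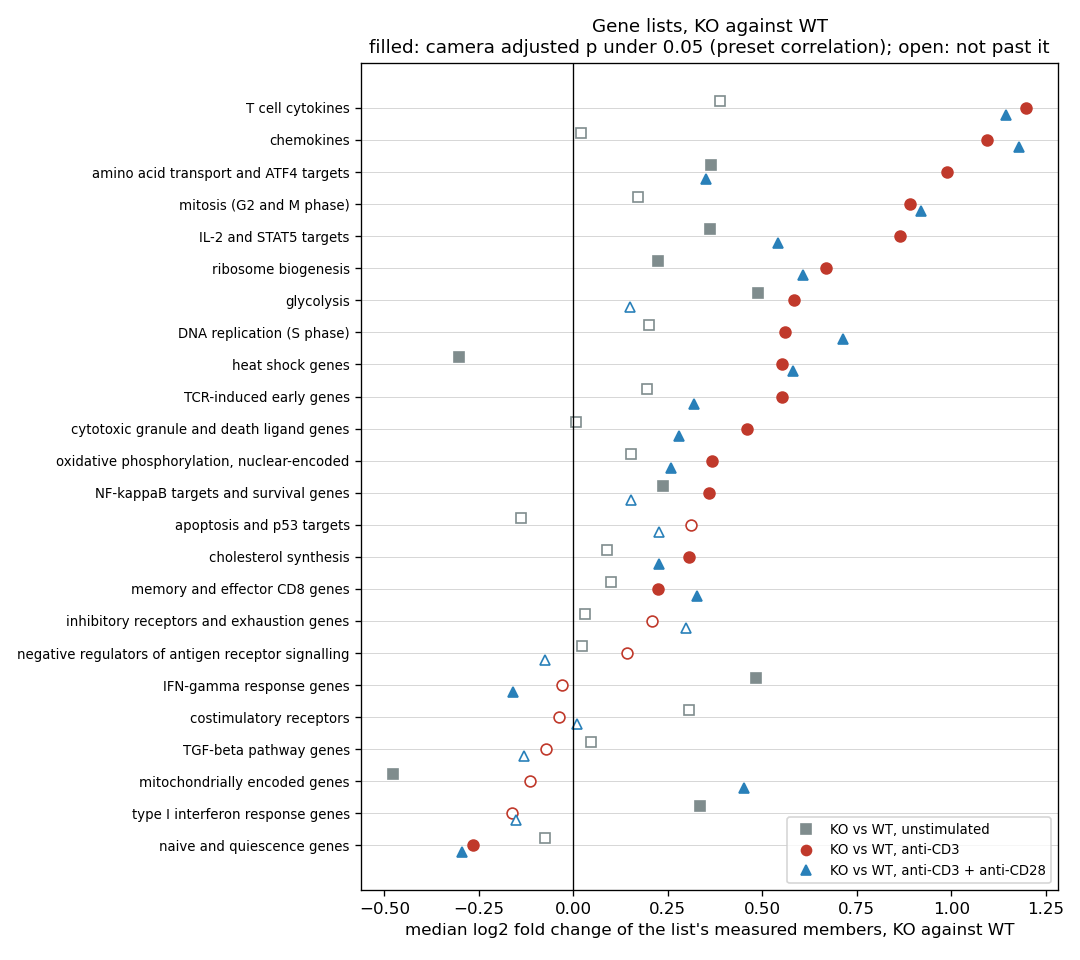
Median log2 fold change of KO against WT cells for 24 gene lists (rows), in unstimulated cells, with anti-CD3 and with both antibodies; filled points passed camera at an adjusted p under 0.05. With anti-CD3 the T cell cytokine list has a median of 1.198 and the IFN-gamma response list -0.030, against 0.39 and 0.48 in unstimulated cells.

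KO and WT both-antibody cells were compared next. Ifng averaged 469.9 ± 222 CPM in KO and 64.1 ± 7.73 CPM in WT cells (2.87 ± 0.37, adjusted p = 0.00165), and Gzmb 206 ± 101 and 27.9 ± 6.33 CPM (2.89 ± 0.48, adjusted p = 0.00425). Csf2, Il2, Tnf and Lif were higher in KO cells by 2.81 ± 0.49, 2.52 ± 0.52, 1.14 ± 0.20 and 3.36 ± 0.47 (adjusted p 0.00195 to 0.00842), and Tnfsf11 (RANK ligand) by 2.26 ± 0.32 (adjusted p = 0.00165). The serpin gene Serpinb6b was higher by 1.43 ± 0.28 (adjusted p = 0.00675). The chemokine genes Ccl3 and Xcl1 were higher by 2.04 ± 0.26 and 1.24 ± 0.17 (adjusted p = 0.00128 and 0.00162). T cell cytokines had 11 of 15 higher and 0 lower (11 and 1 within the list, median 1.14, adjusted p = 3.33e-05, or 0.245 with estimated correlation). Chemokines had 5 of 8 higher and 0 lower (5 and 0 within the list, median 1.18, adjusted p = 0.00293, or 0.278 with estimated correlation). Cytotoxic genes had 4 of 14 higher and 0 lower (5 and 0 within the list, median 0.28, adjusted p = 0.0213, or 0.361 with estimated correlation).

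Among activation genes, Il2ra, Irf4, Nr4a3 and Cd69 were higher by 1.63 ± 0.24, 0.78 ± 0.15, 1.18 ± 0.17 and 0.87 ± 0.23 (adjusted p 0.00177 to 0.0212). TCR-induced early genes had 9 of 23 higher and 1 lower (11 and 2 within the list, median 0.32, adjusted p = 0.00841, or 0.361 with estimated correlation). Eomes, Tbx21 and Cd44 were higher by 1.42 ± 0.18, 1.11 ± 0.18 and 0.95 ± 0.17 (adjusted p 0.000973 to 0.00374). Memory and effector genes had 8 of 29 higher and 1 lower (10 and 3 within the list, median 0.33, adjusted p = 0.0246, or 0.361 with estimated correlation). Cdk6 was higher by 1.96 ± 0.19 (adjusted p = 6.05e-05). IL-2 and STAT5 targets had 11 of 20 higher and 3 lower (12 and 4 within the list, median 0.54, adjusted p = 0.000688, or 0.259 with estimated correlation). Cd200 and the inhibitory receptor gene Havcr2 (TIM-3) were higher by 2.03 ± 0.31 and 1.55 ± 0.51 (adjusted p = 0.00226 and 0.0469). Tgfbr2, Smad7 and the TGF-beta-induced integrin gene Itgae were lower, at -0.46 ± 0.11, -0.66 ± 0.12 and -0.69 ± 0.17 (adjusted p 0.00364 to 0.016). S1pr1 and Txnip were lower, at -0.48 ± 0.089 and -0.66 ± 0.098 (adjusted p = 0.00435 and 0.00206). Naive and quiescence genes had 0 of 24 higher and 10 lower (0 and 12 within the list, median -0.30, adjusted p = 2.34e-06, or 0.245 with estimated correlation).

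DNA replication genes had 18 of 25 higher and 1 lower (20 and 1 within the list, median 0.71, adjusted p = 1.61e-09, or 0.245 with estimated correlation) in KO cells given both antibodies, with Cdc6 and Cdc45 higher by 1.56 ± 0.29 and 1.52 ± 0.29 (adjusted p = 0.00425 and 0.00511). Mitosis genes had 7 of 22 higher and 0 lower (11 and 0 within the list, median 0.92, adjusted p = 0.000187, or 0.361 with estimated correlation), including Top2a (1.58 ± 0.30, adjusted p = 0.00638). Ribosome biogenesis had 20 of 25 higher and 0 lower (22 and 0 within the list, median 0.61, adjusted p = 6.01e-11, or 0.245 with estimated correlation). Dkc1 and Pa2g4 were higher by 1.07 ± 0.20 and 0.82 ± 0.15 (adjusted p = 0.00435 and 0.00367). Amino acid genes had 5 of 21 higher and 0 lower (7 and 0 within the list, median 0.35, adjusted p = 3.33e-05, or 0.259 with estimated correlation), with asparagine synthetase (Asns) and Psat1 higher by 1.74 ± 0.28 and 1.27 ± 0.17 (adjusted p = 0.00243 and 0.00126). Heat shock genes had 11 of 16 higher and 0 lower (11 and 0 within the list, median 0.58, adjusted p = 5.99e-06, or 0.259 with estimated correlation). Hspd1 and Hsp90aa1 were higher by 1.24 ± 0.23 and 1.24 ± 0.21 (adjusted p = 0.00482 and 0.00357).

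IFN-gamma response genes had 1 of 36 higher and 5 lower (1 and 7 within the list, median -0.16, adjusted p = 0.0284, or 0.568 with estimated correlation). This call was lost without WT both-antibody replicate 3 (adjusted p = 0.0929). Tap1, a peptide transporter gene of antigen presentation, was lower, at -0.52 ± 0.16 (adjusted p = 0.0382) and Irf8 higher by 1.17 ± 0.18 (adjusted p = 0.00215). Mitochondrially encoded genes had 1 of 13 higher and 0 lower (0 and 0 within the list, median 0.45, adjusted p = 0.0246, or 0.457 with estimated correlation). This call was lost with the GC correction (adjusted p = 0.389), without KO both-antibody replicate 3 (0.0686) and without WT both-antibody replicate 2 (0.131). The apoptosis gene Bbc3 and the linker histone gene Hist1h1c were among the lowest, at -1.61 ± 0.46 and -1.49 ± 0.46 (adjusted p = 0.0289 and 0.0477). Over all genes 1598 were higher and 1023 lower, and 1810 kept their call and direction among the 2892 called with the GC correction, which ended the calls of Smad7, Tap1, Havcr2 and Cd69 (adjusted p 0.0556 to 0.181). Of the 25 genes fixed in advance 13 were higher and 3 lower. The count was 11 without WT both-antibody replicate 3 and 40 without WT both-antibody replicate 2, where the lone WT sample was assumed to vary like the other groups. Without KO both-antibody replicates 1, 2 and 3 it was 5647, 1101 and 830, and in a fit of these 5 libraries alone 0. Of 39 named genes called, 36 lost their call without WT both-antibody replicate 3 (adjusted p 0.0536 to 0.239; Cblb, Cd200 and Cdk6 kept it), 25 without WT both-antibody replicate 2 (adjusted p 0.0517 to 0.197), 6 without KO both-antibody replicate 3 (adjusted p 0.0625 to 0.182: Itgae, Tap1, Bbc3, Hist1h1c, Havcr2 and Cd69), 5 without KO both-antibody replicate 2 (adjusted p 0.0502 to 0.112: Tap1, Bbc3, Hist1h1c, Havcr2 and Cd69) and 39 in the fit of the 5 libraries alone (adjusted p 0.197 to 0.264). One or more of Tap1, Hist1h1c and Havcr2 also lost their call without any 1 of 10 other libraries (adjusted p 0.05 to 0.0624).

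Unstimulated KO and WT cells were also compared. The cytokine genes Ifng, Tnf and Il2 and the activation genes Gzmb and Il2ra did not pass. Ifng averaged 7.06 ± 0.807 CPM in KO and 8.59 ± 1.80 CPM in WT cells (-0.27 ± 0.34, adjusted p = 0.585), Gzmb 5.03 ± 1.53 and 4.40 ± 2.21 CPM (0.16 ± 0.48, adjusted p = 0.836) and Il2ra 1.12 ± 0.487 and 1.06 ± 0.374 CPM (-0.17 ± 0.36, adjusted p = 0.761). Tnf had 0.27 ± 0.18 (adjusted p = 0.264), and Il2 lay near the detection floor at 0.0462 ± 0.0587 and 0.175 ± 0.182 CPM (adjusted p = 0.172). IFN-gamma response genes had 22 of 36 higher and 0 lower (23 and 0 within the list, median 0.48, adjusted p = 1.67e-08, or 0.625 with estimated correlation). Irf8 and the immunoproteasome gene Psmb9 were higher in KO cells by 1.02 ± 0.18 and 0.78 ± 0.13 (adjusted p = 0.00467 and 0.00466). Type I interferon response genes had 7 of 26 higher and 0 lower (7 and 1 within the list, median 0.34, adjusted p = 0.0124, or 0.625 with estimated correlation). The antiviral genes Oas1a and Bst2 were higher by 1.13 ± 0.24 and 0.84 ± 0.14 (adjusted p = 0.00747 and 0.00381).

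Some genes of metabolism and of T cell function were also higher in unstimulated KO cells. Glycolysis genes had 12 of 20 higher and 0 lower (13 and 0 within the list, median 0.49, adjusted p = 0.000906, or 0.625 with estimated correlation). Gapdh, Gpi1 and the glucose transporter gene Slc2a1 were higher by 0.71 ± 0.13, 0.71 ± 0.14 and 0.67 ± 0.13 (adjusted p 0.00639 to 0.00686). Ribosome biogenesis had 8 of 25 higher and 1 lower (8 and 1 within the list, median 0.22, adjusted p = 0.0153, or 0.625 with estimated correlation). Myc and the replication genes Mcm2 and Mcm5 were higher by 0.88 ± 0.12, 0.54 ± 0.11 and 0.54 ± 0.11 (adjusted p 0.0023 to 0.00728). Amino acid transport and ATF4 targets had 10 of 21 higher and 1 lower (12 and 1 within the list, median 0.37, adjusted p = 0.00435). NF-kappaB targets and survival genes had 11 of 23 higher and 2 lower (11 and 3 within the list, median 0.24, adjusted p = 0.024). IL-2 and STAT5 targets had 7 of 20 higher and 0 lower (7 and 0 within the list, median 0.36, adjusted p = 0.0151). Each had adjusted p = 0.625 with an estimated correlation. The chemokine receptor gene Cxcr3, Id3 and Il2rb were higher by 0.96 ± 0.18, 1.01 ± 0.22 and 0.63 ± 0.12 (adjusted p 0.00592 to 0.00839), the granule protease genes Ctsw and Gzmm by 0.66 ± 0.12 and 1.15 ± 0.20 (adjusted p = 0.00645 and 0.00467), Tbx21 by 0.63 ± 0.16 (adjusted p = 0.0123), and the inhibitory receptor genes Lag3, Pdcd1 and Entpd1 by 1.21 ± 0.28, 0.66 ± 0.20 and 1.09 ± 0.22 (adjusted p 0.00686 to 0.0257).

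Some heat shock and mitochondrially encoded genes were lower in unstimulated KO cells, less so with the GC correction (list medians -0.042 and -0.11, adjusted p = 0.0245 and 0.28). Heat shock genes had 0 of 16 higher and 6 lower (1 and 7 within the list, median -0.30, adjusted p = 0.0151, or 0.625 with estimated correlation). Hspa1b, Hsph1 and Dnaja1 were lower, at -2.14 ± 0.46, -0.58 ± 0.12 and -0.60 ± 0.12 (adjusted p 0.00725 to 0.00915). Mitochondrially encoded genes had 0 of 13 higher and 7 lower (0 and 8 within the list, median -0.48, adjusted p = 0.002, or 0.625 with estimated correlation). The NADH dehydrogenase genes mt-Nd4 and mt-Nd5 were lower, at -0.68 ± 0.18 and -0.68 ± 0.20 (adjusted p = 0.016 and 0.0227). Cd28, Il7r, the ion transporter gene Slc4a10 and Plcxd2 were lower, at -0.51 ± 0.12, -0.48 ± 0.10, -1.12 ± 0.24 and -1.01 ± 0.12 (adjusted p 0.00102 to 0.00946). Plcxd2 lies in the same region as the predicted gene Gm15638, which overlaps it, so their reads may be shared. Among the highest values were those of the histone gene Hist1h4h, Rpph1, the RNA of ribonuclease P, and Terc, the RNA of telomerase, at 2.87 ± 0.84, 2.58 ± 0.82 and 2.01 ± 0.50 (adjusted p 0.0137 to 0.0409).

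Of 16246 genes, 2493 were higher and 1641 lower in unstimulated KO cells, and the log2 fold changes tracked GC content. Across expressed protein-coding genes, which are not independent replicates, Spearman's rho was 0.845 (0.471 with anti-CD3 and -0.654 with both antibodies). With the GC correction 1012 genes were called, 658 of them in the same direction as without it. The corrected medians were 0.37 for IFN-gamma response genes (adjusted p = 8.3e-15) and 0.11 for glycolysis (0.0245). The correction ended the calls of amino acid transport, NF-kappaB and IL-2 and STAT5 targets (adjusted p = 0.276, 0.327 and 0.32) and of mt-Nd4, mt-Nd5, Hist1h4h, Rpph1, Terc, Cd28, Il7r, Lag3 and Pdcd1 (adjusted p 0.0661 to 0.672). Tbx21 had -0.13, in the opposite direction (adjusted p = 0.832). The count of calls was 348 without KO unstimulated replicate 2 and 611 without WT unstimulated replicate 1. Of 32 named genes called, 14 lost their call without KO unstimulated replicate 2 (adjusted p 0.0506 to 0.156: Oas1a, Id3, Dnaja1, mt-Nd4, mt-Nd5, Hist1h4h, Rpph1, Terc, Cd28, Il7r, Lag3, Pdcd1, Tbx21 and Slc4a10), 9 without WT unstimulated replicate 1 (adjusted p 0.0501 to 0.143: Oas1a, mt-Nd4, mt-Nd5, Hist1h4h, Rpph1, Terc, Lag3, Pdcd1 and Tbx21), 3 without WT unstimulated replicate 2 (adjusted p 0.0558 to 0.0803: Hist1h4h, Rpph1 and Pdcd1), and Hist1h4h and Rpph1 without KO unstimulated replicate 1 (adjusted p 0.0573 to 0.0748) or WT unstimulated replicate 3 (adjusted p 0.0545 to 0.0788). Rpph1 also lost its call without any 1 of 7 other libraries (adjusted p 0.0501 to 0.0583), and in a fit of the 6 unstimulated libraries alone Hspa1b, mt-Nd4, mt-Nd5 and Pdcd1 lost theirs (adjusted p 0.0907 to 0.138).

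Several lists in unstimulated cells rested on single libraries. The type I interferon call was lost without KO unstimulated replicate 3 and without WT unstimulated replicate 1 (adjusted p = 0.458 and 0.053). Ribosome biogenesis and IL-2 and STAT5 targets lost theirs without KO unstimulated replicate 3 (adjusted p = 0.0834 and 0.0717), and NF-kappaB targets and heat shock genes without WT unstimulated replicate 2 (adjusted p = 0.0653 and 0.0536). Of the 25 genes fixed in advance, 6 were higher, 3 lower and 16 did not pass.

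The response to anti-CD3 was measured within each genotype against its own unstimulated cells. No culture time is given for these, so culture and stimulation cannot be told apart. The chemokine genes Ccl3 and Xcl1 rose by 7.09 ± 0.31 and 6.34 ± 0.19 (adjusted p = 2.8e-10 and 3.48e-13) in WT cells. KO cells had 8.45 ± 0.32 and 6.69 ± 0.19 (adjusted p = 2.99e-11 and 1.63e-13). Il2ra, Irf4 and Nr4a3 rose by 5.50 ± 0.28, 4.75 ± 0.16 and 3.14 ± 0.16 (adjusted p 7.18e-13 to 8.09e-10) in WT cells. KO cells had 7.16 ± 0.29, 5.09 ± 0.16 and 4.33 ± 0.17 (adjusted p 2.26e-13 to 3.48e-11). Ifng, Gzmb and Tnf rose by 3.41 ± 0.33, 3.56 ± 0.45 and 1.38 ± 0.18 (adjusted p 4e-06 to 7.67e-05) in WT cells. KO cells had 5.98 ± 0.37, 5.69 ± 0.47 and 2.30 ± 0.18 (adjusted p 2.56e-08 to 1.22e-06). Il2 went from 0.175 to 2.62 CPM in WT (adjusted p = 0.000514) and from 0.0462 to 15.3 CPM in KO cells (adjusted p = 4.25e-07). The immediate early gene Fos fell, with -6.25 ± 0.18 (adjusted p = 3.48e-13) in WT cells. KO cells had -5.63 ± 0.18 (adjusted p = 2.26e-13). Cd69 fell in WT cells (-1.11 ± 0.20, adjusted p = 0.000709) and had -0.19 ± 0.20 in KO cells (adjusted p = 0.494, and 0.0139 with the GC correction and 0.0355 with limma voom, within 0.0139 to 0.787 over its alternatives), and its interaction with genotype had adjusted p = 0.198 (0.0213 and 0.0319 without KO both-antibody replicates 1 and 3, 0.0114 with the groups compared alone and 0.0264 with limma voom).

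Among gene lists, IFN-gamma response genes had 29 of 36 higher and 0 lower (30 and 0 within the list, median 1.39, adjusted p = 2e-26, or 0.0417 with estimated correlation) in WT cells given anti-CD3, and 22 of 36 higher and 1 lower (22 and 1 within the list, median 0.72, adjusted p = 3.27e-09, or 0.195 with estimated correlation) in KO cells. Gbp2 rose by 3.50 ± 0.16 (adjusted p = 3.45e-11) in WT cells. KO cells had 3.02 ± 0.15 (adjusted p = 1.75e-10), and Cd274 (PD-L1) rose by 2.97 ± 0.16 (adjusted p = 4.25e-10) in WT cells. Chemokines had 6 of 8 higher and 1 lower (6 and 1 within the list, median 5.79, adjusted p = 5.88e-10, or 0.0417 with estimated correlation) in WT cells. KO cells had 7 of 8 higher and 1 lower (7 and 1 within the list, median 6.67, adjusted p = 1.05e-08, or 0.0638 with estimated correlation). T cell cytokines had 11 of 15 higher and 1 lower (12 and 1 within the list, median 2.36, adjusted p = 6.45e-07, or 0.061 with estimated correlation) in WT cells. KO cells had 11 of 15 higher and 0 lower (12 and 0 within the list, median 2.87, adjusted p = 5.96e-08, or 0.0638 with estimated correlation). Type I interferon response genes had 2 of 26 higher and 16 lower (2 and 16 within the list, median -0.65, adjusted p = 0.00016, or 0.395 with estimated correlation) in KO cells, and the antiviral gene Mx1 fell in both genotypes, with -3.05 ± 0.23 (adjusted p = 3.14e-08) in WT cells. KO cells had -3.12 ± 0.23 (adjusted p = 1.72e-08).

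With anti-CD3 ribosome biogenesis had 10 of 25 higher and 0 lower (17 and 0 within the list, median 0.36, adjusted p = 1.58e-06, or 0.307 with estimated correlation) in WT cells. KO cells had 24 of 25 higher and 0 lower (25 and 0 within the list, median 0.92, adjusted p = 1.38e-12, or 0.143 with estimated correlation), with Nolc1 and Myc up by 0.55 ± 0.10 and 0.71 ± 0.12 (adjusted p = 0.000719 and 0.000434) in WT cells. KO cells had 1.16 ± 0.10 and 1.198 ± 0.12 (adjusted p = 2.09e-07 and 1.05e-06). DNA replication genes had 17 of 25 higher and 1 lower (18 and 1 within the list, median 0.75, adjusted p = 7.32e-06, or 0.259 with estimated correlation) in KO cells, with Mcm5 up by 1.14 ± 0.11 (adjusted p = 5.19e-07). In WT cells mitosis genes had 1 of 22 higher and 5 lower (1 and 8 within the list, median -0.57, adjusted p = 0.0143, or 0.59 with estimated correlation). This call was lost without WT anti-CD3 replicate 2 (adjusted p = 0.111) and without WT unstimulated replicate 1 (adjusted p = 0.0588).

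Pdcd1 and Lag3 rose with anti-CD3 by 3.94 ± 0.18 and 2.06 ± 0.27 (adjusted p = 6.24e-11 and 2.14e-05) in WT cells. KO cells had 3.89 ± 0.17 and 1.82 ± 0.23 (adjusted p = 2.99e-11 and 1.24e-05). Naive and quiescence genes had 6 of 24 higher and 12 lower (6 and 14 within the list, median -0.33, adjusted p = 0.0148, or 0.445 with estimated correlation) in WT cells. KO cells had 3 of 24 higher and 18 lower (4 and 18 within the list, median -0.44, adjusted p = 4.27e-05, or 0.195 with estimated correlation). Cblb itself rose by 0.33 ± 0.081 (adjusted p = 0.00631) in WT cells. KO cells had 0.28 ± 0.082 (adjusted p = 0.013). The latter call was lost without KO anti-CD3 replicate 3, KO unstimulated replicate 1 or KO unstimulated replicate 3 (adjusted p = 0.0516, 0.0586 and 0.0658).

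In all, 1829 genes rose and 2127 fell with anti-CD3 in WT cells, and 3185 and 2804 in KO cells. Of these, 1362 rose in both (359 for independent lists) and 1609 fell in both (367). These comparisons share no library. With both antibodies 2890 rose and 2648 fell in WT, and 3731 and 3648 in KO cells. Ifng, Gzmb, Il2ra and Tnf rose by 2.91 ± 0.35, 2.71 ± 0.47, 5.30 ± 0.29 and 1.19 ± 0.19 (adjusted p 2.67e-09 to 0.00104) in WT cells. KO cells given both antibodies had 6.05 ± 0.37, 5.44 ± 0.47, 7.09 ± 0.29 and 2.06 ± 0.18 (adjusted p 4.49e-11 to 1.86e-06). The WT count with both antibodies was 2909 without WT both-antibody replicate 2 and 2712 without replicate 3. Of the 25 genes fixed in advance, 15 rose and 3 fell with anti-CD3 in WT cells and 16 and 3 in KO cells. With both antibodies 13 and 3 did so in WT, and 18 and 3 in KO cells.

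**Figure D3:**
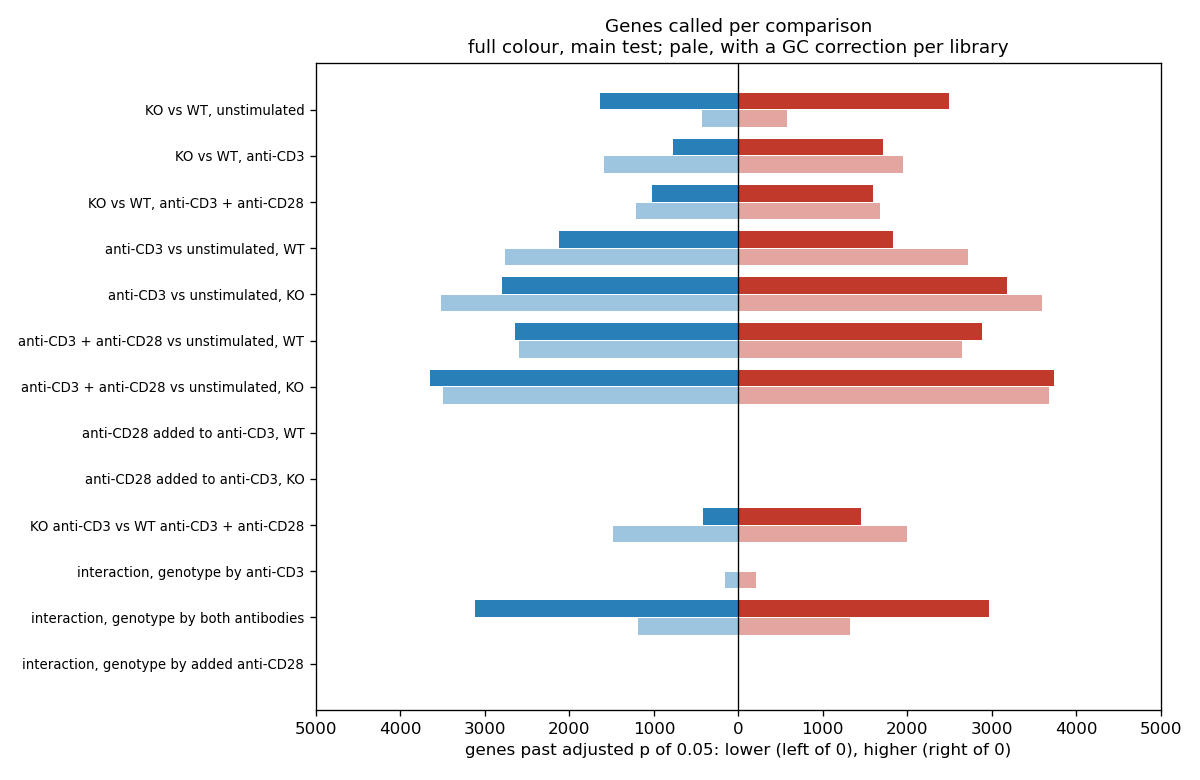
Number of genes past an adjusted p of 0.05 in each of 13 comparisons, higher and lower drawn to opposite sides of 0, from edgeR's quasi-likelihood test. The bars reach 1713 higher and 779 lower for KO against WT cells given anti-CD3, and 0 for anti-CD28 added to anti-CD3 in either genotype.

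Adding anti-CD28 to anti-CD3 was tested within each genotype. Il2, a classical target of costimulation, was at 2.78 ± 0.472 CPM with and 2.62 ± 0.876 CPM without anti-CD28 in WT cells (0.048 ± 0.52, adjusted p = 0.967, 95% interval -1.05 to 1.15), and at 15.96 ± 9.36 and 15.3 ± 3.59 CPM in KO cells (0.054 ± 0.40, adjusted p = 0.967, 95% interval -0.80 to 0.91). The log2 fold changes of Ifng, Gzmb, Il2ra and Myc were -0.49 ± 0.33, -0.85 ± 0.44, -0.20 ± 0.23 and 0.46 ± 0.14 (adjusted p 0.147 to 0.634) in WT cells. KO cells had 0.074 ± 0.29, -0.25 ± 0.37, -0.064 ± 0.20 and -0.40 ± 0.12 (adjusted p 0.547 to 0.932). Lag3 had 0.67 ± 0.25 (adjusted p = 0.172) in WT and Pdcd1 -0.55 ± 0.15 (adjusted p = 0.547) in KO cells. Myc passed in WT cells without KO both-antibody replicate 1 (adjusted p = 0.0459) and without KO both-antibody replicate 3 (adjusted p = 0.0413). In a fit of the compared groups alone Ifng, Gzmb and Myc passed in WT cells (adjusted p 0.00042 to 0.00613), and by limma voom Gzmb, Myc and Lag3 in WT and Myc and Pdcd1 in KO cells (adjusted p 0.000106 to 0.0239).

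No gene passed by edgeR in either genotype, with 3506 genes at an unadjusted p under 0.05 in WT and 1460 in KO cells (smallest adjusted p 0.135 and 0.547). DESeq2 called 565 genes in WT and 0 in KO cells, and limma voom with quality weights 6058 and 5550. EdgeR called 4 and 0 with the GC correction and 4780 and 0 on the groups compared alone. Without KO both-antibody replicate 1, replicate 3 and WT anti-CD3 replicate 3 edgeR called 1187, 1434 and 1 in WT cells. Without the first it called 628 in KO cells. On counts simulated without a GC trend 79.1% (WT) and 88.1% (KO) of 2-fold changes were called, and 41.8% and 47.8% of 1.5-fold changes. The real WT count moved with libraries outside the comparison, so these shares do not show that changes were absent. In KO cells camera placed glycolysis, ribosome biogenesis, DNA replication, cholesterol synthesis and TCR-induced early genes lower (medians -0.36, -0.24, -0.24, -0.11 and -0.21; adjusted p = 7.59e-06, 3.8e-05, 0.000274, 0.00312 and 0.00406; each adjusted p = 0.442 with an estimated correlation), with 0 members called over all genes of 20, 25, 25, 24 and 23 measured (6, 7, 5, 0 and 0 lower within the list). Without KO both-antibody replicate 1 the adjusted p of the last 4 was 0.325, 0.299, 0.299 and 0.311, and without KO anti-CD3 replicate 3 that of the last 3 was 0.0638, 0.167 and 0.172. The GC correction ended the call of TCR-induced early genes (adjusted p = 0.278). Spearman's rho of the log2 fold changes with GC content was 0.818 in WT and -0.826 in KO cells. With fry none of the 5 passed (adjusted p 0.0608 to 0.137).

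KO cells given anti-CD3 alone were also set against WT cells given both antibodies. Ifng, Gzmb, Il2 and Csf2 were higher in the KO cells by 2.80 ± 0.36, 3.14 ± 0.48, 2.47 ± 0.52 and 2.58 ± 0.48 (adjusted p 0.000506 to 0.0073). Il2ra, Irf4 and Cd200 were higher by 1.69 ± 0.24, 0.85 ± 0.15 and 2.17 ± 0.31 (adjusted p 0.000506 to 0.00195), and Tgfbr2, Smad7 and Cblb lower, at -0.45 ± 0.11, -0.60 ± 0.12 and -1.15 ± 0.090 (adjusted p 5.37e-06 to 0.0131). T cell cytokines had 11 of 15 higher and 0 lower (11 and 0 within the list, median 1.38, adjusted p = 2.57e-07). Ribosome biogenesis had 23 of 25 higher and 0 lower (25 and 0 within the list, median 0.84, adjusted p = 6.24e-20). DNA replication had 21 of 25 higher and 0 lower (23 and 0 within the list, median 0.88, adjusted p = 3.8e-16). Naive and quiescence genes had 0 of 24 higher and 12 lower (0 and 15 within the list, median -0.36, adjusted p = 2.72e-10). Each of these had adjusted p = 0.0482 with an estimated correlation. Over all genes 1455 were higher and 415 lower (77.8% higher), against 1995 and 1486 with the GC correction (57.3% higher) and 1633 and 796 with DESeq2. The count was 679 without KO anti-CD3 replicate 3, 323 and 334 without WT both-antibody replicates 2 and 3, and 2811 without KO both-antibody replicate 3, which enters only the shared estimate of spread. Of 10 named genes, Tgfbr2 lost its call without KO anti-CD3 replicate 3 (adjusted p = 0.0782), Il2, Tgfbr2 and Irf4 without WT both-antibody replicate 2 (adjusted p 0.069 to 0.0852) and Il2, Csf2 and Tgfbr2 without replicate 3 (adjusted p 0.0827 to 0.145).

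Whether loss of Cbl-b resembles added costimulation was asked across 16246 genes, which are not independent replicates. The KO against WT difference with anti-CD3 was correlated with the anti-CD28 effect in WT cells, both measured from the WT anti-CD3 libraries. Pearson's r was 0.456 and the covariance 0.181. In 20 simulations of unchanged groups that shared their simulated controls, r averaged 0.407 (SD 0.0225, range 0.361 to 0.452). The simulated covariance averaged 0.0656, 0.116 below the observed one. With the GC correction r was 0.373 and the covariance 0.127. The simulations were drawn and fitted without that correction, so they give no reference for the corrected values. Leaving out 1 library gave r of 0.408 to 0.537 and covariances of 0.157 to 0.250. The simulations kept all libraries. The 3 control libraries cannot be divided into sets of at least 2. Part of the excess may come from the shared controls or the GC trend, which both differences followed. No overlap of calls was counted because edgeR on all libraries called no gene for anti-CD28.

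The KO against WT differences in the 3 states share no libraries. With anti-CD3 and with both antibodies 583 genes were higher in KO cells in both (168 for independent lists) and 126 lower in both (49.1). With the GC correction these counts were 1041 (201) and 617 (119). Unstimulated cells and cells given anti-CD3 shared 782 higher (263) and 358 lower genes (78.7), and 272 (69.4) and 207 (42.2) with the GC correction. Unstimulated cells and cells given both antibodies shared 96 (245) and 35 (103), and 61 (59.8) and 45 (32.4) with the GC correction.

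Interactions tested whether the response to stimulation depended on genotype, as its log2 fold change in KO cells minus that in WT cells. For anti-CD3, 9 genes passed (8 with a larger and 1 with a smaller value in KO cells), with 2399 at an unadjusted p under 0.05. Cd200, Cish and Plk2 had 2.21 ± 0.39, 2.14 ± 0.37 and 2.01 ± 0.33 (adjusted p 0.0376 to 0.0479), and Cdk6, Igfbp4, Hsph1, Ccnd2 and Umps 1.72 ± 0.22, 1.32 ± 0.20, 1.14 ± 0.17, 0.85 ± 0.14 and 0.80 ± 0.14 (adjusted p 0.00887 to 0.0441). Ifng had 2.57 ± 0.45 (adjusted p = 0.0502; 5.08e-05 to 0.18 over its alternatives), and passed without KO both-antibody replicate 1 (adjusted p = 0.0016), without KO both-antibody replicate 3 (adjusted p = 0.0186), with the GC correction (adjusted p = 0.0298) and with DESeq2, limma voom, the CPM filter, the groups compared alone, and the replicate number as a block over all libraries or within genotype (adjusted p = 0.0272 and 0.00447). With the block over all libraries Cd200, Plk2 and Umps lost their call (adjusted p 0.0532 to 0.0544), and with relative log expression scaling Cd200 and Umps (adjusted p = 0.0553 for each). Gzmb and Il2ra had 2.13 ± 0.61 and 1.66 ± 0.42 (adjusted p = 0.19 and 0.146), and Il2, near 0 counts before stimulation, adjusted p = 0.171. Il2ra passed without KO both-antibody replicate 1 or 3 (adjusted p = 0.0372 and 0.023), and Il2 without KO both-antibody replicate 1 (adjusted p = 0.032), and both with the groups compared alone and with DESeq2 (adjusted p = 0.00611 and 0.00422), which also called Gzmb (0.0417). DESeq2 called 263 genes and edgeR with the GC correction 368, 9 of them shared with the uncorrected fit.

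By list, IFN-gamma response genes responded less to anti-CD3 in KO cells, with 0 of 36 higher and 1 lower (1 and 24 within the list, median -0.64, adjusted p = 1.65e-16, or 0.144 with estimated correlation). Ribosome biogenesis had 0 of 25 higher and 0 lower (19 and 0 within the list, median 0.52, adjusted p = 1.56e-11, or 0.155 with estimated correlation). Heat shock genes had 1 of 16 higher and 0 lower (13 and 0 within the list, median 0.63, adjusted p = 8.63e-11, or 0.144 with estimated correlation). DNA replication had 0 of 25 higher and 0 lower (13 and 0 within the list, median 0.52, adjusted p = 4.58e-08, or 0.164 with estimated correlation). T cell cytokines had 0 of 15 higher and 0 lower (6 and 0 within the list, median 0.93, adjusted p = 6.65e-06, or 0.144 with estimated correlation). The 8 named genes all lost their call without WT anti-CD3 replicate 1 (adjusted p 0.0585 to 0.139), WT anti-CD3 replicate 2 (adjusted p 0.0518 to 0.0959) or WT unstimulated replicate 2 (adjusted p 0.0561 to 0.101), and 7 of them, all but Cdk6, without any 1 of 9 other libraries (adjusted p 0.0504 to 0.169). Without WT unstimulated replicate 1, KO unstimulated replicate 3 and KO unstimulated replicate 2 the numbers lost were 4 (adjusted p 0.0853 to 0.156), 3 (adjusted p = 0.0733) and 2 (adjusted p = 0.0725). The count of calls was 329 without KO both-antibody replicate 1, 366 without KO both-antibody replicate 3, 20 without KO unstimulated replicate 2 and 0 to 8 without any other 1 library.

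For both antibodies, 6089 genes passed the interaction (2972 with a larger and 3117 with a smaller value in KO cells). Ifng, Gzmb, Cd200 and Il2ra had 3.14 ± 0.48, 2.73 ± 0.65, 2.70 ± 0.42 and 1.80 ± 0.43 (adjusted p 0.00339 to 0.00745), and Psmb9, Hist1h4h and Rpph1 -1.19 ± 0.20, -4.74 ± 1.17 and -4.44 ± 1.19 (adjusted p 0.00339 to 0.0134). Gzmb lost its call without the 2 libraries of most extreme GC tilt (2.02, adjusted p = 0.0618). IFN-gamma response genes had 1 of 36 higher and 21 lower (1 and 21 within the list, median -0.52, adjusted p = 1.18e-05, or 0.81 with estimated correlation) and heat shock genes 12 of 16 higher and 0 lower (13 and 0 within the list, median 0.85, adjusted p = 1.76e-05, or 0.81 with estimated correlation). GC-corrected, 2500 genes passed, 1585 of them as before, and without WT both-antibody replicates 2 and 3 the counts were 3815 and 4010. For added anti-CD28, 1 gene passed, Nob1, a ribosome assembly gene, at -1.22 ± 0.18 (adjusted p = 0.0482). Its call was lost without any 1 of 13 libraries (adjusted p 0.0502 to 0.204), and with relative log expression scaling, the CPM filter, either block or the groups compared alone. DESeq2 called 2287 genes, and the edgeR count was 4753 without KO both-antibody replicate 1, 1240 without KO unstimulated replicate 2 and 0 to 2 without any other 1 library.

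Markers of other cell types were summed per library. The labels' protocol states a CD8+ purity of over 99% for the stimulated cells. B cell markers summed to 357 ± 33.0 CPM in WT and 440.0 ± 42.1 CPM in KO unstimulated cells, of which Ighm, the immunoglobulin mu gene, made up 313 and 382 CPM. With anti-CD3 the B cell sums were 263 ± 18.1 and 226 ± 16.8 CPM. Myeloid and dendritic cell markers, led by Cst3 (13.2 and 16.2 CPM unstimulated), summed to 36.1 ± 2.64 and 42.2 ± 0.894 CPM unstimulated and 36.9 ± 0.441 and 37.5 ± 1.35 CPM with anti-CD3. CD4 and regulatory T cell markers, led by Cxcr5 (24.5 and 37.9 CPM), summed to 44.5 ± 2.68 and 61.6 ± 4.09 CPM unstimulated. NK and gamma-delta T cell markers, led by Klra7 (9.61 and 5.63 CPM), summed to 36.4 ± 4.15 and 27.9 ± 5.02 CPM, and erythroid and platelet markers to 3.68 ± 2.72 and 4.79 ± 1.35 CPM. Stromal and endothelial markers summed to 148 ± 10.9 and 161 ± 18.2 CPM, nearly all from Pecam1 (148 and 160.0 CPM), which T cells also express.

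None of these lists passed camera between KO and WT cells in any state. The calls with anti-CD3 were 3 higher and 0 lower of 16 (3 and 0 within the list; adjusted p = 0.421) for B cell and 0 of 11 (adjusted p = 0.378), 0 of 8 (adjusted p = 0.349), 0 of 10 (adjusted p = 0.114), 0 of 4 (adjusted p = 0.905) and 0 of 1 (adjusted p = 0.212) for myeloid, CD4, NK, erythroid and stromal markers, none higher or lower over all genes and only the stromal gene lower within the list. The erythroid median and mean (0.78 and 1.49) differed in sign from the test. Unstimulated, the adjusted p values of the B cell, myeloid, CD4, NK, erythroid and stromal lists were 0.19, 0.446, 0.19, 0.239, 0.446 and 0.681, and with both antibodies 0.44, 0.567, 0.43, 0.235, 0.776 and 0.28. B cell markers passed, as higher in unstimulated KO cells, without WT unstimulated replicate 1 (adjusted p = 0.0156). NK and gamma-delta T cell markers passed, as lower with anti-CD3, without KO anti-CD3 replicate 3 (adjusted p = 0.0274) and without WT anti-CD3 replicate 1 (adjusted p = 0.014).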

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

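Of the tests in this part, those on GC content for the interactions, on other cell types and on DNA linked to the knockout allele were chosen only after the result was seen. By interaction tests the response to stimulation differed between KO and WT cells. For anti-CD3 9 genes passed, with log2 values, among others, of 2.21 for Cd200, 2.14 for Cish, 2.01 for Plk2, 1.72 for Cdk6, 1.32 for Igfbp4, 1.14 for Hsph1, 0.85 for Ccnd2 and 0.80 for Umps. For both antibodies 6089 passed, among them Ifng (3.14), Gzmb (2.73, not called without the 2 libraries of most extreme GC tilt, adjusted p = 0.0618), Cd200 (2.70), Il2ra (1.80), Psmb9 (-1.19), Hist1h4h (-4.74) and Rpph1 (-4.44), and for added anti-CD28 1, Nob1 (-1.22). Lists that differed for anti-CD3 were IFN-gamma response (adjusted p = 1.65e-16), ribosome biogenesis (1.56e-11), heat shock (8.63e-11), DNA replication (4.58e-08) and T cell cytokine genes (6.65e-06), and for both antibodies IFN-gamma response (1.18e-05) and heat shock genes (1.76e-05). With an estimated correlation none of these lists passed (adjusted p 0.144 to 0.81).

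The count for both antibodies, 6089, tracked GC content, with Spearman's rho of -0.826 across expressed protein-coding genes, which are not independent replicates. The GC correction left 1585 of these genes (26.0%) called in the same direction, so the trend as a whole cause is argued against. Another 79 were called in the opposite direction. The 4425 no longer called had a median absolute log2 value of 0.84 (median SE 0.23) before and 0.21 (0.14) after the correction, so for them the GC trend may be part of the cause and the calls ended because the values shrank. Those called in the same direction shrank too, from 1.06 to 0.66. Without the 2 libraries with the most extreme GC tilt 3773 genes passed, which argues against those 2 as the source of the whole count. A genotype effect on the response remains open for the genes called in the same direction.

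IFN-gamma response genes were higher in unstimulated KO cells (median 0.48) and rose less with anti-CD3 in KO cells (interaction median -0.64). Neither list result passed with an estimated correlation (adjusted p = 0.625 and 0.144), and 1 of 36 members passed the interaction over all genes, so the pattern itself is uncertain. With the GC correction the interaction median was -0.58, which argues against the GC trend. In unstimulated cells the median log2 fold changes of B cell and myeloid markers were 0.169 ± 0.175 and 0.172 ± 0.262 (SE). The list had 0.483 ± 0.0749, above the myeloid value by little more than the SE of that value. These medians were not GC-corrected, though this contrast followed GC content, so the test leaves those cells open. A CD8+ purity of over 99% is stated for stimulated cells. CD4 and regulatory T cell markers, outside that test, summed to 61.6 ± 4.09 CPM in KO and 44.5 ± 2.68 CPM in WT cells and passed fry (adjusted p = 0.0179) but not camera (0.19), so cells of those types stay open. The IFN-gamma receptor genes, named outside the rule for this test, had -0.19 ± 0.091 (Ifngr1, adjusted p = 0.181) and -0.16 ± 0.12 (Ifngr2, adjusted p = 0.419) in KO against WT cells given anti-CD3, short of the 0.3 decrease (log2) set in advance, which argues against lower receptor expression as the source. The interaction subtracts the unstimulated KO against WT difference (0.48), which makes up much of the smaller rise (-0.64). The cause of that difference stays open.

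Near Cblb, 5 of 77 tested genes within 10 Mb differed between KO and WT cells in the same direction in all 3 states, named here after their values were seen: Cd96, Cd200r1, Plcxd2 and the predicted gene Gm15638, which overlaps Plcxd2, were lower and Cmss1 was higher. After the GC correction 3 of them (Cd96, Gm15638 and Plcxd2) stayed called in all 3 states, which argues against the GC trend for those, while Cd200r1 unstimulated went from -0.94 ± 0.26 to -0.61 ± 0.26 (adjusted p = 0.162) and Cmss1 unstimulated went from 0.76 ± 0.25 to 0.64 ± 0.25 (adjusted p = 0.14). Of 16087 windows centred on other genes, 1.32% held as many such genes (at most 6). DNA linked to the knockout allele that differs from the WT strain is a candidate source, but it cannot be told apart from an effect of Cbl-b on these genes, because the KO and WT groups differ in both.

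Other splits of the same libraries were counted for each contrast of 3 against 3. Counts are from edgeR, and the 10 splits are too few for a share under 0.05. The real counts and the highest of the other splits were 4134 and 0 for KO against WT unstimulated, 2492 and 0 with anti-CD3, 3956 and 0 for anti-CD3 in WT cells, 5989 and 0 for anti-CD3 in KO cells, 7379 and 1946 for both antibodies in KO cells, and 0 and 0 for added anti-CD28 in KO cells, where all 10 splits gave as many. In each of the others 1 split, the real one, gave as many. For the interaction with anti-CD3, 2 of 60 splits, the real one included, gave at least 9 genes. The other grouped KO unstimulated replicate 1 with WT unstimulated replicates 1 and 3 and gave 798. It kept the anti-CD3 libraries in their genotypes, so their KO against WT difference (2492 genes) enters it. Other splits that kept them gave 7 and 2. Every split that mixed them gave 0. Mixing puts that difference into the spread, so the share of splits cannot judge chance.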

How the results depend on the processing

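Of these settings the GC correction and the fit without KO both-antibody replicate 3 and KO unstimulated replicate 2 were chosen after seeing the data; the others were planned. Gene values named in the text mostly kept their direction and side of the threshold: 225 of 229 with relative log expression scaling, 226 of 229 with the CPM filter, 221 of 229 with no filter, 222 of 227 with DESeq2, 216 of 229 with limma voom, 218 of 229 without those 2 libraries, 207 of 229 with the GC correction (15 lost and 6 gained a call), 171 of 228 with only the groups compared (45 lost and 12 gained a call) and 3606 of 3893 over the fits that left out 1 library (271 lost and 16 gained a call). Tbx21 in unstimulated cells reversed, from 0.63 to -0.13 with the GC correction. Of 95 list results, 59 lost their call with an estimated correlation, 10 with fry and 6 with the GC correction, and 7 and 1 gained one with fry and the GC correction. Those gained with fry were, with anti-CD3, inhibitory receptors (adjusted p = 0.0092), negative regulators (0.0141), apoptosis genes (0.0115), CD4 markers (0.0404) and stromal markers (0.0337), CD4 markers unstimulated (0.0179) and stromal markers with both antibodies (0.0352). Those lost with fry, besides 5 for added anti-CD28 in KO cells, were type I interferon response, ribosome biogenesis and heat shock genes unstimulated (0.105, 0.0925 and 0.0514) and IFN-gamma response and mitochondrially encoded genes with both antibodies (0.199 and 0.0959). Without those 2 libraries Pdcd1 and NF-kappaB targets unstimulated, Tap1, Bbc3, Hist1h1c, Havcr2 and Cd69 with both antibodies and Gzmb in the both-antibody interaction lost their call (adjusted p 0.0579 to 0.16), and Tcf7, Tgfbr2, Smad7 and mitochondrially encoded genes with anti-CD3 and Myc for added anti-CD28 in WT cells gained one (0.00487 to 0.0428). Over all lists 136 calls became 10 with an estimated correlation, and the correlation between the KO and CD28 effects went from 0.456 to 0.373 with the GC correction. The cause of these changes was not tested.

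Counts of genes past the threshold, by edgeR unless another tool is named, moved by more than 1.5 times as follows. With limma voom they were 5742 for KO against WT with anti-CD3, 9370 for KO against WT with both antibodies, 8425 for both antibodies in WT cells, 6058 for added anti-CD28 in WT cells, 5550 for added anti-CD28 in KO cells, 5924 for KO anti-CD3 against WT both-antibody cells, 918 for the anti-CD3 interaction and 7681 for the anti-CD28 interaction. With only the groups compared they were 5262 for KO against WT with anti-CD3, 0 for KO against WT with both antibodies, 3990 for both antibodies in KO cells, 4780 for added anti-CD28 in WT cells, 4725 for KO anti-CD3 against WT both-antibody cells, 475 for the anti-CD3 interaction and 0 for the anti-CD28 interaction. DESeq2 gave 565 for added anti-CD28 in WT cells, 263 for the anti-CD3 interaction and 2287 for the anti-CD28 interaction. With no filter there were 24 for added anti-CD28 in WT cells, 63 for the anti-CD3 interaction and 326 for the anti-CD28 interaction, and with relative log expression scaling and with the CPM filter 0 for the anti-CD28 interaction. The GC correction gave 1012 for KO against WT unstimulated, 4 for added anti-CD28 in WT cells, 3481 for KO anti-CD3 against WT both-antibody cells, 368 for the anti-CD3 interaction, 2500 for the both-antibody interaction and 11 for the anti-CD28 interaction, and the fit without the 2 libraries 4229 for KO against WT with anti-CD3, 1526 for KO against WT with both antibodies, 4734 for both antibodies in KO cells, 2932 for added anti-CD28 in WT cells, 3388 for KO anti-CD3 against WT both-antibody cells, 136 for the anti-CD3 interaction, 3773 for the both-antibody interaction and 1067 for the anti-CD28 interaction. Fitting only the groups compared uses fewer libraries to estimate the spread; otherwise the cause was not tested.

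Leaving out 1 library at a time gave 348 to 5465 genes for KO against WT unstimulated, 853 to 3528 for KO against WT with anti-CD3, 11 to 5647 for KO against WT with both antibodies, 2949 to 4665 for anti-CD3 in WT cells, 4783 to 6712 for anti-CD3 in KO cells, 2712 to 6461 for both antibodies in WT cells, 5461 to 8421 for both antibodies in KO cells, 0 to 1434 for added anti-CD28 in WT cells, 0 to 628 for added anti-CD28 in KO cells, 323 to 2811 for KO anti-CD3 against WT both-antibody cells, 0 to 366 for the anti-CD3 interaction, 3815 to 7382 for the both-antibody interaction and 0 to 4753 for the anti-CD28 interaction. The calls over all lists were 125 to 145, and the correlation of the KO and CD28 effects 0.408 to 0.537. Where WT cells given both antibodies were left with 1 library, that sample was assumed to vary like the other groups.

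It is open whether replicate numbers pair the samples. Deviations from group means correlated above 0.1 in 14 of 40 same-number library pairs (median r 0.0275, -0.542 to 0.710) and 22 of 80 others. Of 17 libraries 9 correlated best with their own number. The GC trend may mask pairing. With the replicate number as a block the count for the anti-CD28 interaction was 0, the other counts moved by at most 1.5 times (the anti-CD3 interaction to 6), 221 of 229 gene values kept their call (6 lost and 2 gained a call: Rpph1 unstimulated, Hist1h1c with both antibodies, Nob1, and Cd200, Plk2 and Umps in the anti-CD3 interaction lost theirs, and Tgfbr2 with anti-CD3 and Ifng in that interaction gained one) and so did 94 of 95 list results (the other was the IFN-gamma response with both antibodies, adjusted p = 0.0553). With a block within genotype the count was 31 for the anti-CD3 and 0 for the anti-CD28 interaction.

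Depth limited the precision of low genes most: near 0 counts, as for Il2 in unstimulated cells, a fold change rests on the prior count.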
